A study of Homo sapiens with 2 samples.

How the data were processed

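Gene expression was measured on 2 one-colour oligonucleotide arrays, 1 of parental EBC1 cells and 1 of the resistant subline EBC1-R. Per the labels' protocols, total RNA was extracted from frozen cells with Trizol, and 100 ng was made into biotin-labelled cDNA with an Affymetrix whole-transcript kit. The extraction protocol in the labels names an HG-U133 array with 22282 probe sets. The deposited table holds 28869 probe sets, and its identifiers match a probe annotation of a different Affymetrix array, a whole-transcript gene array, so the statement in the extraction protocol does not describe these values.

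The authors deposited 1 value per probe set and array, taken here as log2 intensities. The log base, background correction, summarization, normalization and software are not given in the sources used here. The log2 scale was inferred from the range of the deposited values, 4.21 to 14.1 in EBC1 and 4.22 to 14.2 in EBC1-R. The medians of the deposited columns were 6.73 and 6.71, and the sorted columns differed by at most 0.17 at any rank, so the arrays had been brought to nearly the same distribution before deposit. Such scaling removes any change shared by most genes. In 548 probe sets, 1.90% of the total, the deposited values of both arrays were identical, while 809 others differed by no more than 0.01. No detection calls were used, so low intensities are not separated from background, and differences that start from a low intensity understate the change in transcript.

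The probe annotation gave 1 gene symbol for 19310 probe sets, several for 1752 and none for 7807. Only probe sets with 1 symbol entered the gene table. Symbols were looked up by gene identifier in a RefSeq gene table (assembly GRCh38.p14), which held 19279 of these probe sets and changed no symbol. Values of several probe sets of a gene were averaged, which gave 18377 genes, 685 of them with more than 1 probe set. Among the 374 multi-probe-set genes above the level filter (875 probe sets), the pooled SD of the difference between probe sets of the same gene was 0.16 on the log2 scale. This SD describes agreement within a pair of arrays and not variation between cultures. Whether probe sets of the same gene share probes, which would lower the SD, was not checked. The build behind the array design was not given, so the RefSeq table was used for gene order only and no coordinates are printed.

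There was 1 array per group. No test between the groups was possible, no p-value was computed, and no value has a replicate error. The number of arrays limits the precision. For each gene the difference is log2 EBC1-R minus log2 EBC1. A gene passed the level filter when its higher value reached 7.41, the median of the genes' higher values, which 9189 genes did. A gene that differs can thus pass through 1 array alone. List medians over members above the filter can therefore be partly selected by the difference itself. The threshold for counting was a difference of 1 log2 unit, or 2-fold. A total of 36 gene lists was fixed before the data were examined, with 1027 entries, of which 915 were found (870 distinct genes, 44 of them in more than 1 list). The median difference of each list, over all its measured members, was placed among the medians of 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean intensity. A list was called above or below its matched range outside the central 95% of those medians (the 2.5th and 97.5th percentiles). About 1.8 of the 36 lists would fall outside by chance if lists did not share genes and genes of a list were independent, which they are not. The percentiles describe this pair of arrays. Neighbouring genes were compared in windows of 15 consecutive genes that passed the level filter, and the median of each window was set against the highest and lowest window of 1000 shuffles of the gene order.

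Genes were named by a rule fixed before the data were examined. It took ABCB1 and MET, the 15 genes with the largest increase and the 15 with the largest decrease above the level filter (without small RNAs, pseudogenes, readthrough loci and uncharacterised loci), up to 4 members of each list with the largest difference, and the genes of the lists and windows around ABCB1, MET and other runs of neighbours. Genes outside the rule are marked as chosen after their values were seen. The alternatives were quantile normalization, centring on the median, removal of a lowess trend on intensity (span 0.2), a pseudocount of 16 on the linear scale, other level filters, the brightest probe set in place of the mean, a 3-fold threshold, unmatched random lists, windows of 10 and 25 genes, windows over all genes, and window means of differences limited to 1 log2 unit either way. In a simulation over 18377 genes, differences were drawn from a normal distribution with the robust SD of the differences between these 2 arrays, so it shows how the counting works under that noise and holds no variation between cultures. In it, 99.0% of genes planted with a 2.83-fold change were counted as at least 2-fold different and 0 of 8989 unchanged genes were. In the same simulation 4.5% of unshifted lists of 30 genes fell outside the central 95%, and 84.0% of lists shifted by 0.15 were found above it. In a window simulation over 9180 genes, 96.0% of 50 runs of 15 neighbours shifted by 0.8 were found above 200 shuffles. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.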

Results

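EBC1 is a human lung squamous cell carcinoma line with an amplified MET gene, which encodes the receptor tyrosine kinase for hepatocyte growth factor. EBC1-R is a subline selected from it in rising concentrations of the MET kinase inhibitor PHA-665752 and kept in 3 µM inhibitor. Whole-transcript arrays of the parental line (1 array) and of EBC1-R (1 array) were compared to find transcripts that accompany resistance. Because EBC1-R was kept in inhibitor, resistance and exposure to the drug were not separated by the design. There were no replicates, so each value below is a single measurement with no error, and differences are given as sizes without a test. Levels are log2 intensities as deposited. Across 18377 genes the arrays correlated with Pearson's r = 0.98, a correlation across genes, which are not independent replicates. Among the 9189 genes above the level filter, 95% of differences lay between -0.85 and 0.92 log2 units.

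ABCB1, which encodes the drug efflux pump P-glycoprotein, had the largest difference of all genes above the level filter. Its level was 5.37 in EBC1 and 12.65 in EBC1-R, a difference of 7.27 log2 units or 155-fold. In EBC1 the ABCB1 value stood at the 22.2nd percentile of all probe sets and in EBC1-R at the 99.5th. No detection call was used, so whether the EBC1 value exceeds background is not known. ABCB1 is named in the title of the study of these samples. How the study chose it is not given in the sources used here, so its direction is not counted as independent evidence. MET itself was at 13.17 in EBC1 and 13.21 in EBC1-R, a difference of 0.04, and lay among the brightest transcripts of both arrays.

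In all, 196 genes were at least 2-fold higher and 153 at least 2-fold lower in EBC1-R. After ABCB1, the largest increases were in CFB (complement factor B), 14.9-fold, TMEM45A, 10.4-fold, AKR1C2 (an aldo-keto reductase), 10.2-fold, and HMOX1 (heme oxygenase), 9.72-fold. The 3 probe sets of CFB all differed in the same direction. Whether they share probes was not checked, so their agreement is not counted as separate support. AKR1C2 has close paralogs, and hybridisation of their transcripts to its probes was not tested. CCDC80 was 8.30-fold higher, ABI3BP 7.37-fold, complement C3 7.33-fold, the chemokine CCL2 7.07-fold and LCN2 (lipocalin) 6.95-fold. IL6 was 6.87-fold higher, CROT (a peroxisomal carnitine acyltransferase) 6.38-fold, PDZK1IP1 6.34-fold, the protease inhibitor SLPI 6.22-fold and IGFBP3, which binds insulin-like growth factors, 6.10-fold. Of these, TMEM45A, ABI3BP and CCL2 were in the lowest 30% of probe sets in EBC1, with levels of 5.19, 5.63 and 5.75.

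The largest decreases were in CALB2 (calretinin), 7.21-fold lower in EBC1-R, and FST (follistatin, an activin antagonist), 7.14-fold lower. ENPP1 was 5.76-fold lower, the ETS factor ETV1 5.74-fold, the semaphorin receptor PLXNA4 5.49-fold, the urea transporter SLC14A1 5.38-fold and BLID 5.16-fold. DUSP6, a phosphatase that dephosphorylates ERK, was 5.03-fold lower, from 11.08 to 8.75. ETV4 was 4.22-fold lower, the integrin subunit ITGB8 4.11-fold, and MANSC1 differed by -2.07 log2 units. TMC7 was 3.94-fold lower, ACP7 3.75-fold, SPNS2, a sphingosine-1-phosphate transporter, 3.71-fold and FGFBP1 3.68-fold.

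**Figure D1:**
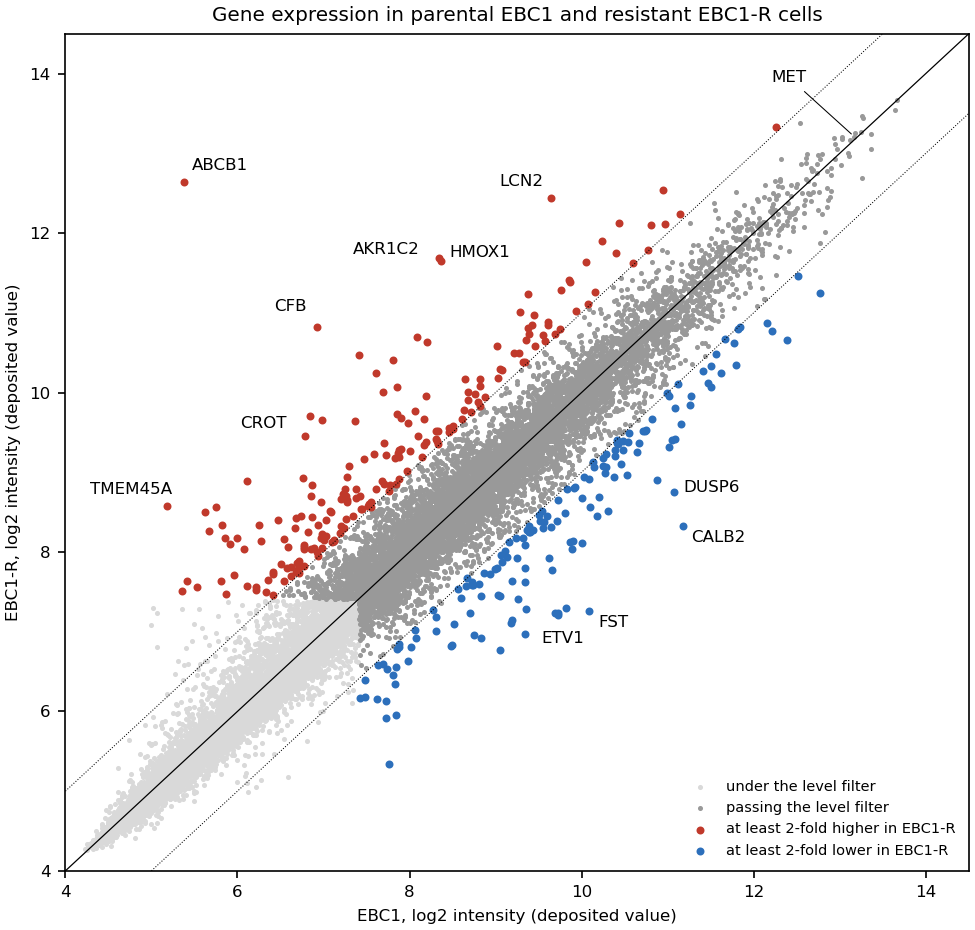
Deposited log2 intensity of each gene in EBC1 (x axis) and EBC1-R (y axis), 1 point per gene, 1 array per axis; the solid line marks equal values and the dotted lines a 2-fold difference. ABCB1 stands apart at 5.37 and 12.65, while MET lies on the line at 13.17 and 13.21.

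Most measured genes of the drug transport and metabolism lists were higher in EBC1-R, few of them 2-fold and several by small amounts from low levels. Of 17 measured members of the ABC transporter list, not all of them multidrug pumps, 12 were higher. ABCB1, and ABCB4 at 2.05-fold, were the 2 members at least 2-fold higher. The 12 include ABCC10 (0.02), ABCG2 (0.06) and ABCB5 (0.11), named after their values were seen, with ABCG2 and ABCB5 under the level filter. ABCB4 went from 5.56 to 6.60, under the level filter on both arrays, and is a close paralog of ABCB1. ABCC4 was 1.88-fold and ABCC5 1.80-fold higher. The list's median difference was 0.19, at the 99.9th percentile of matched random lists, and 0.46, also above the range, over the 10 members above the level filter. Both values include ABCB1, which is not counted as independent evidence, and the first includes ABCB4. The list also shares 3 genes with the NRF2 list. Members such as ABCB1 and ABCC4 (6.61 in EBC1) pass the filter through EBC1-R alone, so the filtered median is no independent support. The percentile was not computed without ABCB1 and ABCB4. Of 34 drug metabolism genes, 22 were higher and 5 at least 2-fold: the cytochromes P450 CYP1B1 (6.05-fold), CYP3A4 (4.50-fold, 5.07 to 7.24 and under the level filter) and CYP1A1 (4.22-fold), the oxidase AOX1 (3.35-fold) and CYP4F11 (2.17-fold, named after its value was seen). The median was 0.10, above the matched range, which ended at 0.03. It lay between GSTA4 (5.02 to 5.13) and FMO1 (4.82 to 4.92), both under the level filter and named after their values were seen. The median over all members thus rests on small differences at low intensity. Over the 9 members above the level filter the median was 0.88, also above the range. CYP1A1 (6.25 in EBC1) and AOX1 (6.68) pass that filter through EBC1-R alone, so the larger median is partly selected by the change and is no independent support.

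Transcripts that follow ERK activity were lower in EBC1-R. Of 27 measured ERK output genes, 24 were lower, 13 of them at least 2-fold, including ETV1, DUSP6, ETV4 and ETV5 (3.61-fold lower). The median difference was -0.95, which is 1.93-fold lower and below all 10000 matched random lists. IL1A (3.44-fold) and CXCL8 (2.23-fold), both also in the inflammatory list, were the 2 members at least 2-fold higher and were named after their values were seen. Among 32 receptor tyrosine kinases only EPHA2 differed at least 2-fold, at 2.46-fold lower. MST1R was 1.73-fold and AXL 1.64-fold lower, and the median of -0.01 lay within the matched range. Of 31 ligands and related factors, FGFBP1, HBEGF (2.85-fold) and EFNB2 (2.24-fold) were lower, KITLG was 2.04-fold higher, and the median of -0.08 lay within the range.

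Proliferation genes were lower by a smaller amount. Of 42 members 39 were lower, with a median of -0.40 (1.32-fold) below all random lists, and 2 passed 2-fold: cyclin CCNE2, 2.32-fold, and MYBL2, 2.21-fold. AURKB was 1.96-fold and RRM2 1.92-fold lower. Sterol and fatty acid synthesis genes were lower in 24 of 25 members, with a median of -0.46 (1.37-fold), also below all random lists. The desaturases FADS2 (2.71-fold) and SCD (2.12-fold) and the sterol sensor INSIG1 (2.14-fold) were at least 2-fold lower, and fatty acid synthase FASN was 1.83-fold lower. Replication-dependent histones had a median of -0.16, within the matched range, with H3C2 2.21-fold lower. That list lay below the range after lowess (-0.15), above the level filter (-0.27) and with unmatched random lists. The median of p53 targets (-0.04) lay within it too, with CDKN1A 2.13-fold and SESN2 2.16-fold lower and PLK2 2.34-fold higher. Apoptosis regulators had a median of -0.07, within range. BMF, which promotes apoptosis, was 2.40-fold higher, and the survival genes BCL2L1 and MCL1 were 2.03-fold and 2.01-fold lower.

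Inflammatory genes formed the list with the highest median, 0.86 (1.81-fold), above all 10000 random lists, and 1.26 over the 21 members above the level filter. Members low in EBC1, such as CCL2 (5.75) and IL6 (6.11), pass that filter through EBC1-R alone, so the larger median is partly selected by the change. Of 33 cytokines and NF-kB targets, 25 were higher and 15 at least 2-fold, led by C3, CCL2, IL6 and the mitochondrial superoxide dismutase SOD2 (3.67-fold). LIF, which is also an ERK output gene, was the 1 member at least 2-fold lower, at 2.90-fold, and was named after its value was seen. Interferon response genes were higher in 30 of 38 members, with a median of 0.40. At least 2-fold higher were IFIT1 (2.70-fold), IFIT2 (2.55-fold), TRIM22 (2.49-fold, under the level filter), IFIT3 (2.46-fold) and IFI6 (2.30-fold, named after its value was seen). Antigen presentation genes were higher in 13 of 16 measured members, median 0.30. The class II genes HLA-DPA1 and HLA-DPB1 were 3.18-fold and 2.78-fold higher, and CD274, which encodes PD-L1, was 2.40-fold lower. Both medians lay above the matched range. Markers of other cell types did not move with these genes: the median difference was -0.08 over 15 leukocyte, -0.04 over 12 fibroblast and -0.05 over 12 endothelial markers, all within range and none with a member 2-fold different.

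Stress and metabolic lists were also higher. Of 32 hypoxia and glycolysis genes, 26 were higher and 8 at least 2-fold, with a median of 0.51. The oxygen-sensing hydroxylase EGLN3 was 4.86-fold, the glycolytic regulator PFKFB3 3.28-fold, BNIP3 2.95-fold and P4HA1 2.87-fold higher. Of 27 NRF2 targets, which serve antioxidant defence, 26 were higher, with a median of 0.42; besides AKR1C2 and HMOX1, AKR1C3 was 3.12-fold and GCLM, of glutathione synthesis, 2.29-fold higher. Both lists lay above all random lists. Of 30 ER stress and amino acid response genes, 8 were at least 2-fold higher, among them PDIA4 (3.24-fold), CRELD2 (2.83-fold), DNAJC3 (2.36-fold) and SDF2L1 (2.16-fold), which act in protein folding in the endoplasmic reticulum. SESN2 was the 1 member at least 2-fold lower, and the median was 0.21, above the range. Members moved both ways: PSAT1 (1.85-fold), ASNS (1.73-fold), CHAC1 (1.56-fold) and ATF4 (1.10-fold), named after their values were seen, were lower. The median of the pooled list therefore does not show that its amino acid response members were higher. Lysosomal genes (median 0.24 over 29) and cytosolic ribosomal proteins (0.15 over 29) lay above the range with no member 2-fold different. CTSS, under the level filter, was 1.67-fold, CTSL 1.60-fold and RPL10A 1.40-fold higher. Oxidative phosphorylation genes (0.10 over 31) and reference genes (0.02 over 12) lay within it, the former above it after the lowess trend was removed (0.13) and with unmatched random lists. Reference genes differed by up to 1.82-fold, lower for PPIA, and TFRC was 1.77-fold higher.

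**Figure D2:**
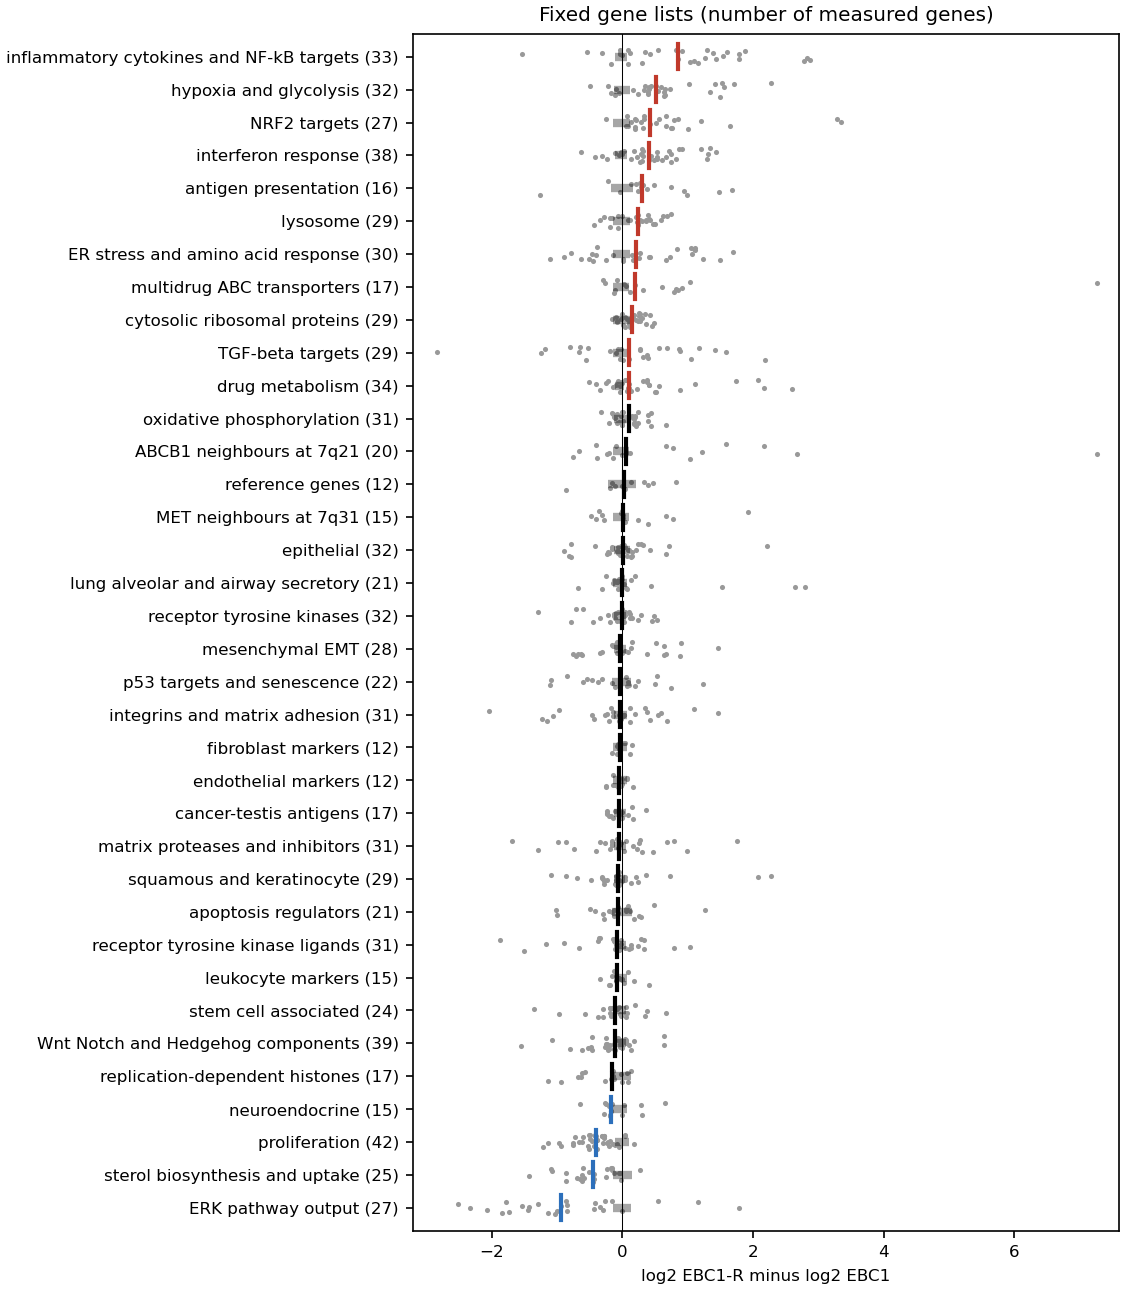
Difference between EBC1-R and EBC1 (x axis, log2) for the measured members of each fixed gene list (grey points, 1 per gene). Vertical bars are list medians, red above, blue below and black within the central 95% of medians of matched random lists (grey horizontal bars). The inflammatory list has the highest median, 0.86, and the ERK output list the lowest, -0.95.

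Most lists for cell state lay within their matched ranges over all members, but several did not over the members above the level filter. Of 24 stem cell associated genes, 16 were lower, with a median of -0.11 within the matched range, though below it with the brightest probe set of each gene (-0.15). NT5E (CD73) was 2.55-fold and ITGA6 1.97-fold lower, while CD24 was 1.59-fold higher. Mesenchymal genes (28, median -0.03) and epithelial genes (32, median 0.00) lay within range. FSTL1 was 2.76-fold higher among the former. Among the latter the epithelial transcription factor ELF3 was 4.62-fold higher, and the keratins KRT19 and KRT8 were 1.86-fold and 1.77-fold lower. Squamous genes had a median of -0.07, with the serpins SERPINB4 and SERPINB3 4.85-fold and 4.22-fold higher from levels near 5, both under the level filter, and SPRR1B 2.13-fold lower. Only 6 of its 29 members passed the level filter, with a median of -0.40, below the range. The airway secretory list had a median of 0.00, with LCN2, SLPI and AGR2 (2.86-fold) at least 2-fold higher, and FOXA2 1.61-fold lower. Only 6 of its 21 members passed the level filter, with a median of 0.80, above the range. Besides the 4 above, these were MUC4 (0.07) and FOXA1 (-0.26), named after their values were seen. That median lies between the members at least 2-fold higher and the rest, and describes neither. Neuroendocrine genes lay below the range, median -0.17, but only 3 of 15 passed the level filter and none differed 2-fold. TGF-beta targets lay just above it, median 0.10, with members on both sides: ID3 was 4.53-fold, THBS1 3.02-fold and ID2 (under the level filter) 2.66-fold higher, and FST was lower. Above the level filter alone, that list's median was -0.06 and within range. Wnt, Notch and Hedgehog components (-0.12, JAG1 2.95-fold lower), integrins and matrix adhesion genes (-0.04, ITGA5 2.76-fold higher and ITGB4 2.34-fold lower), matrix proteases (-0.06, MMP7 3.37-fold higher and ADAM19 3.23-fold lower) and cancer-testis antigens (-0.05) lay within range. The Wnt, Notch and Hedgehog list lay below its range above the level filter (-0.23) and with unmatched random lists.

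Genes next to ABCB1 on chromosome 7 were higher together with it. In chromosomal order ELAPOR2 was 5.75-fold, DMTF1 1.71-fold, TMEM243 3.00-fold, TP53TG1 4.52-fold and CROT 6.38-fold higher, followed by ABCB4 and ABCB1. Directly beyond ABCB1, RUNDC3B differed by -0.14, SLC25A40 by -0.67, DBF4 by -0.75, ADAM22 by 0.06 and SRI by 0.11, with SLC25A40 and SRI alone of these above the level filter. Further on that side ZNF804B, under the filter, was 1.59-fold higher and CDK14 2.32-fold higher, while the 4 genes above the filter from STEAP1 to GTPBP10 were lower, by up to 1.33-fold. On the other side, before ELAPOR2, GRM3 (under the filter) differed by -0.09 and SEMA3A by 0.04, and beyond these PCLO was 1.82-fold and SEMA3C 2.56-fold higher. The fixed list of 20 genes between GRM3 and CDK14, which spans both sides and does not include ELAPOR2, had a median of 0.06, within its matched range. It had 6 members at least 2-fold higher, among them ABCB1, which the study's title names, and CDK14 at the far end. The fixed list around MET had a median of 0.01 over 15 genes, also within range. CFTR was its 1 member 2-fold different, 3.80-fold higher, from 5.35 to 7.28 and under the level filter, and ST7 was 1.70-fold higher.

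A scan of 8857 windows of 15 neighbouring genes found 10 with a median above 0.72, the highest in 1000 shuffles, and none below the lowest, -0.61. The lowest window of the real order was at -0.58. Of the 10, 7 overlapped and lay around ABCB1, with a highest median of 0.77, and 3 lay at the end of the short arm of chromosome 12, with a highest median of 0.85. In the latter run KDM5A, a histone demethylase, was 2.97-fold higher, the kinase WNK1 2.42-fold, RAD52, of homologous recombination, 2.88-fold, ERC1 2.87-fold and DCP1B 2.41-fold. The antisense transcript NINJ2-AS1 was 3.17-fold higher, whereas NINJ2 beside it, under the level filter, differed by -0.24 and B4GALNT3 next to NINJ2 by 0.09. WNT5B, within the run and also under the filter, differed by -0.003. ADIPOR2 was 1.95-fold, CCDC77 1.80-fold and FBXL14 1.79-fold higher, and FOXM1 at the far end was 1.42-fold lower. With windows of 25 genes only the run on chromosome 12 passed, in 3 windows. With all genes in the table, 19 windows lay above the highest shuffled window, on chromosomes 7 and 12, and 10 lay below the lowest, all on chromosome 6.

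**Figure D3:**
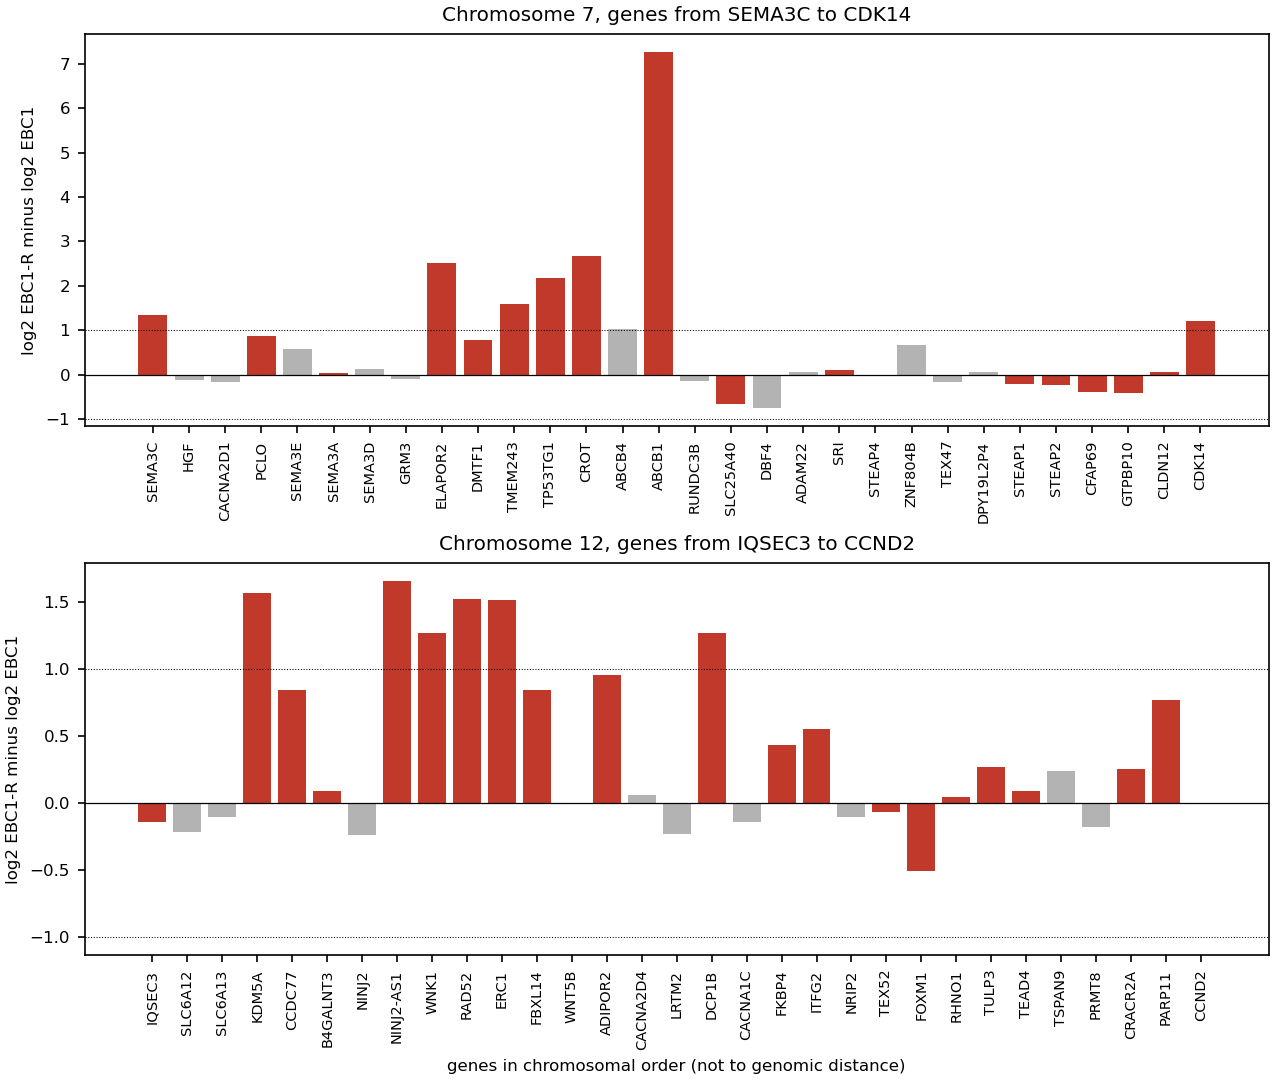
Difference between EBC1-R and EBC1 (y axis, log2) of genes in chromosomal order around ABCB1 (top) and at the end of the short arm of chromosome 12 (bottom); 1 bar per gene, red above and grey under the level filter, dotted lines at 2-fold. Bars are high at each gene from ELAPOR2 to ABCB1 and lower directly beyond it, SEMA3C and CDK14 being high further away, and on chromosome 12 most red bars from KDM5A to DCP1B lie above 0.8, B4GALNT3 being an exception at 0.09.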

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

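The tests of sequence shared between paralogs, of a gain of the long arm of chromosome 7, of MET transcript loss and of other cell types were chosen after the results were seen. The others were set out before their values were computed. With 1 array per group, outlying samples and differences between contrasts could not be looked for.

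Probe sets outside the gene table held further differences. Among 7807 probe sets without a listed gene, 22 above the level filter were at least 2-fold higher in EBC1-R than in the parental control, by up to 2.29 log2 units, and 17 were at least 2-fold lower, down to -2.84. Among 1752 probe sets that name several genes, 22 were at least 2-fold higher, by up to 2.02, and 8 lower, down to -2.93.

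Neighbouring genes were higher together at the ABCB1 locus and at the end of 12p. Hybridisation of ABCB1 transcript to probes of its paralog could raise ABCB4. Of the 18 other members of the fixed list of ABCB1 neighbours, which are not ABC transporters, 4 were at least 2-fold higher. CDK14 at the far end was among them. The central 95% of matched random lists held 0 to 2. The values of these genes had been seen when this test was chosen, so the count is no independent support for a regional increase. For ABCB4 itself, 1.04 higher and under the level filter, a real increase and hybridisation of ABCB1 transcript cannot be told apart with 1 probe set. Gains of whole arms were argued against by a median of 0.017 over 265 other genes of the long arm of chromosome 7 (from RCC1L on) and of 0.047 over 121 genes of 12p beyond the run, and an intensity-dependent bias by a median of 0.84 for the 12p run after the trend was removed, still above every shuffled window. A focal copy number gain in the resistant line and a regional change in transcription remain open as hypotheses, untested because no DNA was measured in the data used here.

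ERK pathway output genes were lower in EBC1-R. Removal of the intensity-dependent trend between the arrays moved the median only from -0.95 to -0.93, still below all matched random lists. Those lists were already matched on mean intensity, so this check adds little to the main comparison. Loss of the MET transcript was argued against by a MET difference of 0.037, where genes of like intensity had a spread of 0.29. MET has 1 probe set, near the top of both arrays, and whether saturation hides a smaller decrease was not tested. Inhibitor in the medium of EBC1-R may hold ERK activity down, but that is confounded with resistance here and was not tested.

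Inflammatory and complement genes were higher in EBC1-R. Leukocytes or fibroblasts among the EBC1-R cells would have raised their markers, but the median differences were -0.081 and -0.044, with median levels of 5.75 and 5.99 in EBC1-R against a level filter of 7.41. LCP1 and CD68, at 11.84 and 11.45 in EBC1-R, were the leukocyte markers above the filter, and both were also bright in EBC1. Removal of the intensity-dependent trend left the list median at 0.86. The random lists were already matched on mean intensity, so here too the check adds little. A change within the cells, through resistance or drug exposure, stays open and untested.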

How the results depend on the processing

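No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. The 2-fold counts (196 higher, 153 lower) stayed within 1.5 times under quantile normalization, median centring, lowess, the pseudocount, no level filter and the brightest probe set. With both values required above the median, 105 genes were higher, by construction fewer since genes low in EBC1 drop out, and 112 were lower. At 3-fold, 58 were higher and 36 lower. Each rescaling moved the median of all genes, -0.03 as deposited, by under 0.1. ABCB1's difference fell from 7.27 to 6.81 with a pseudocount of 16, which compresses low intensities by construction, and was 7.25 to 7.29 under the other scalings. Lists above and below their range numbered 11 and 4 as deposited, 11 to 12 and 4 to 6 under the alternatives, and the 15 called lists kept their side except TGF-beta targets, and the neuroendocrine list, which had too few members above the level filter to be rerun there. Above that filter the airway secretory list (median 0.80) moved above its range and the squamous (-0.40), histone (-0.27) and Wnt, Notch and Hedgehog (-0.23) lists below it. The brightest probe set put the stem cell list (-0.15) below its range. Lowess put the histone list (-0.15) below and oxidative phosphorylation (0.13) above their ranges. Unmatched random lists did the same and put the Wnt, Notch and Hedgehog list below. The number of windows beyond all shuffles, 10, became 3 with windows of 25 genes, 29 with all genes in the table (19 above, on chromosomes 7 and 12, and 10 below, all on chromosome 6) and 6 with window means of differences limited to 1 log2 unit, which changes the statistic and caps the differences together; the causes were not tested. Of 785 values of other named genes under alternatives, 771 moved by less than the spread of genes of like intensity, 14 moved further, all with the pseudocount, and none was reversed. Background intensity limits the folds of genes under the filter.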

Other observations

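The hypothesis below was tested on genes chosen after CYP1A1 and CYP1B1 were seen, and its prediction was written before the median of the list was computed, when the genes with at least 2-fold differences had already been seen and none of these targets was among them. The genes in the next paragraph were chosen after their values were seen.

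Further differences lay outside the fixed lists. Among genes higher in EBC1-R were the serpin SERPINB7 (6.03-fold), PDK4, which inhibits pyruvate dehydrogenase (5.39-fold), the acute phase inhibitor SERPINA3 (3.62-fold) and the leukotriene pathway gene ALOX5AP (3.90-fold). Lower were SOX9, a transcription factor of epithelial progenitors (2.84-fold), the extracellular sulfatase SULF2 (3.45-fold) and FOXQ1 (3.33-fold). The microRNA loci MIR221 and MIR222, which lie in a common cluster, were 3.03-fold and 2.48-fold lower, and MIRLET7A2 was 5.65-fold lower beside BLID, at 5.16-fold. These probe sets report transcription across the loci, and mature microRNAs were not measured here.

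CYP1A1 and CYP1B1, both textbook targets of the aryl hydrocarbon receptor, were 4.22-fold and 6.05-fold higher. The hypothesis that this receptor was active in EBC1-R predicts that its other targets would be higher too. Over 5 measured ones (TIPARP, CYP1A2, NQO1, ALDH3A1 and NFE2L2) the median difference was 0.082, at the 81.9th percentile of matched random lists, which neither meets the prediction nor excludes it. TIPARP differed by 0.30, and CYP1A2 by -0.41 and ALDH3A1 by -0.16, both under the level filter.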
